A study of Homo sapiens with 11 samples.

How the data were processed

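Total RNA of HaCaT keratinocytes was isolated with Trizol and RNeasy columns with DNase I, and biotin-labelled cRNA was made with a MessageAmp kit, per the labels. The samples were 6 vehicle arrays (0, 0.5, 1, 3, 6 and 12 h) and 5 obacunone arrays (0.5, 1, 3, 6 and 12 h), with 1 array per agent and time. Nothing in the labels says whether the arrays came from separate cultures. The dose of 100 uM, the vehicle of 0.1% DMSO and the times were taken from the labels.

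The deposited signal table holds a linear signal intensity for 34686 features on each array, not normalised between arrays per the file headers. Beside each signal the deposited table gives a detection p-value, per the file headers. The authors' processed values are on a log2 scale, which was found from the values. They equal the quantile-normalised log2 of the deposited intensity to within 0.00067, and the median of every array is 6.16. The scanner software, and any background correction or combination of probes before the deposited table, are not given in the sources used here. For 25897 features (74.7%) every detection p-value is a multiple of 1 in 770, as a rank among 770 negative controls gives (tolerance 0.002 steps). The other 8789 features have at least 1 p-value between such steps and look like values combined over several probes. The median signal was 68.1 to 74.5 per array and 38.6% to 41.5% of features were detected, with log2 values of any 2 arrays correlated across features at r of 0.977 to 0.994.

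The signals were processed with limma 3.58.1 in R 4.3.3. The mean (59.0 to 64.7) and SD (8.8 to 10.4) of each array's background were estimated from the detection p-values of the features on whole steps, normexp correction was applied with an offset of 16, and the arrays were quantile normalised on the log2 scale. The offset makes fold changes of dim genes smaller than the true ones. Features with a detection p-value under 0.05 on at least 3 arrays were kept (15409). Gene names came from the platform annotation, which was checked against the reference gene table by gene identifier: 20673 identifiers matched and 0 symbols changed. Of all features, 20699 had 1 symbol, 8 had several and 13979 had none. Features with several symbols were left out, and the 4537 kept features with no symbol were fitted on their own. Of 10870 kept features with 1 symbol, 305 genes had more than 1, and the feature with the highest mean stood for the gene, which left 10556 genes.

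All comparisons were fitted with limma lmFit and eBayes, and p-values were adjusted by the method of Benjamini and Hochberg over all genes tested, with a threshold of 0.05 and 2-sided tests. The average effect had time as a block and agent as a term (4 residual degrees of freedom). A second fit had separate agent terms for early (0.5 and 1 h) and late (3, 6 and 12 h) times and their difference (3 residual degrees of freedom). The vehicle course was a slope on log2 of hours plus 1 over the 6 vehicle arrays. With no replicate at any time, the p-values rest on the spread between arrays across times. This includes real changes of the effect with time. Whether it covers the spread between cultures is not known, since the labels do not describe the cultures. The eBayes step also draws each gene's variance toward that of all genes. At each single time, genes at least 2-fold apart and detected on the array with the higher value were counted with no test. Comparisons, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except those named as chosen after.

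The 24 gene lists were cholesterol synthesis and uptake, NRF2 targets, AHR targets, ATF4 and CHOP stress response, chaperones of the endoplasmic reticulum and unfolded protein response, heat shock, immediate early, ERK feedback, inflammatory and NF-kB, interferon response, keratinocyte differentiation, basal keratinocyte, mitosis, DNA replication, p53 targets, LXR targets and fatty acid synthesis, hypoxia and glycolysis, metallothioneins, TGF-beta and YAP targets, BCL2 family, circadian clock, ribosome biogenesis, glucocorticoid and p38-JNK stress, and other cell types. They were tested with camera of limma at a preset correlation between genes of 0.01 and with an estimated correlation, and with fry. The fry values are those of its directional test, except where its mixed test, which counts changes in either direction, is named. Camera compares a list with all other genes, and p-values were adjusted over the 24 lists. At each time the median of a list was set against 10000 random lists of the same size (1000 for sets over 100 genes), drawn from 20 bins of mean expression.

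Named genes were up to 15 with the largest rise and 15 with the largest fall among those past the test with the same sign at every time of the contrast, for the late and the average effect. For each single time they were the 8 largest in each direction, and for the vehicle course the 8 steepest slopes in each direction and the 8 largest rises at 0.5 and 1 h. Where none passed, the 5 with the smallest p in each direction were given. Each list gave up to 4 members with the largest late effect and any member past the threshold. Genes with provisional symbols and those whose symbol starts with SNOR, RNU, MIR, RNY or RN7S were counted and not named, while other small RNA genes, such as TERC and the SCARNA genes, fell under the rule. Genes outside the rule are named only where this is said.

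The steps were tested on simulated data of the same size with 200 changed genes. A 2-fold change was recovered in 100% of genes for the average and the late effect, 90% for the early effect, 62% for late minus early and 74% for the vehicle course, and a 1.41-fold change in 66%, 38%, 18%, 12% and 8%. With no gene changed, 0 genes were called. With 200 changed, unchanged genes made up 8 of 191 calls for the average, 15 of 184 for the late, 7 of 161 for the early, 14 of 151 for the late minus early and 9 of 150 for the vehicle course. The simulated noise was independent between genes, which that of arrays is not. Its size came from the variances after the eBayes step, and each simulated obacunone change was the same at every time of its contrast. Real effects that vary with time may be recovered less often.

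Alternatives were no background correction, normexp with an offset of 50, scaling to the 75th percentile, cyclic loess, no detection filter, detection on all 11 arrays, the authors' values, the mean of a gene's features, an intensity trend with a robust prior, other time terms, fold thresholds of 1.5 and 3, and leaving out each pair or array. A filter on signal, the small RNA level of each array as a covariate and leaving out the 0.5 and 12 h pairs were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.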

Results

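Gene expression was measured in HaCaT cells, an immortalised human keratinocyte line, on Illumina bead arrays that received biotin-labelled cRNA. The cells were given fresh medium with serum and either 100 uM obacunone, a limonoid found in citrus fruit, or 0.1% DMSO as the vehicle. RNA was collected with each agent after 0.5, 1, 3, 6 and 12 h, and with vehicle at 0 h. This made 11 arrays, 5 with obacunone and 6 with vehicle. Each agent and time had 1 array, so no time point had a replicate, and the number of arrays limits the precision. Between 13391 and 14403 of the 34686 deposited features were detected on each array. After a filter on detection, 10556 genes were compared. Differences are given as log2 obacunone minus vehicle, with the standard error of the limma fit after the ± sign. The error comes from the spread between the pairs of arrays at different times, after each gene's variance was drawn toward that of all genes. In the late fit the shared variance had 9.57 degrees of freedom and the gene's own pairs 3. For a gene whose difference changed with time, the error can be smaller than its own spread gives.

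The late comparison asked which transcripts differed between obacunone and vehicle at 3, 6 and 12 h (n = 3 pairs). Genes of cholesterol synthesis and its control made up 8 of the 20 rises. INSIG1, which encodes a membrane protein that restrains sterol synthesis, rose 3.85-fold (log2 1.94 ± 0.23, adjusted p = 0.00222). The enzyme genes HMGCS1 (1.65 ± 0.18), IDI1 (1.64 ± 0.22), MSMO1 (1.62 ± 0.18), MVD (1.46 ± 0.18), DHCR7 (0.94 ± 0.14), SQLE (0.92 ± 0.16) and SC5D (0.86 ± 0.14) rose as well, with adjusted p from 0.00165 to 0.0394. NMRAL2P, a transcribed pseudogene, had the largest rise of all genes tested, 3.91-fold (1.97 ± 0.17, adjusted p = 0.000456). TXNRD1, a thioredoxin reductase, rose 3.08-fold (1.62 ± 0.19, adjusted p = 0.0022), and HMOX1, a heme oxygenase, rose 2.47-fold (1.31 ± 0.15, adjusted p = 0.00165). CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor (AHR), rose 2.40-fold (1.26 ± 0.19, adjusted p = 0.013).

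Other late rises were those of LPIN1, a phosphatidate phosphatase (1.60 ± 0.16, adjusted p = 0.00129), DNAJB9, a chaperone of the endoplasmic reticulum (1.19 ± 0.16, adjusted p = 0.00487), MSC, a transcription factor (1.12 ± 0.15, adjusted p = 0.00757), NOXO1, a subunit of an NADPH oxidase (0.93 ± 0.17, adjusted p = 0.0492), and SPACA6 (0.84 ± 0.14, adjusted p = 0.036). TXNIP, which binds and inhibits thioredoxin, fell to 0.469 of its vehicle level (-1.09 ± 0.16, adjusted p = 0.0105). SGK1, a kinase gene induced by serum and glucocorticoids, fell as well (-0.86 ± 0.15, adjusted p = 0.0416). The other 3 rises were MXD1 (0.88 ± 0.15), GABARAPL1 (0.83 ± 0.15) and MIR25 (1.36 ± 0.23), which were chosen after their values were seen. All 22 genes past the test differed in the same direction at 3 of 3 times.

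In the limma fit, 22 of 10556 genes passed, 20 up and 2 down, and 1068 had an unadjusted p under 0.05. Some named calls depended on the processing. CYP1A1 passed in 10 of 17 alternatives, with 0.63 and no call with no background correction. CYP1A1 was not detected on all 11 arrays, so the size of its rise may not be exact. NOXO1 passed in 8 of 18 alternatives and SGK1 in 9 of 18. Of the cholesterol genes, SQLE passed in 10 of 18, DHCR7 in 12 and IDI1 in 13, against 16 each for HMGCS1 and MSMO1. HMOX1 passed in 14 of 18, with differences of 0.65 to 1.40. The count was 7 without the 3 h pair, 10 without the 6 h pair and 50 without either the 0.5 h or the 1 h pair. With 1 early pair left, the early term fits it exactly, so these last 2 give the same late fit. The late estimates stay as they were, and the spread between the early pairs leaves the error. It was 11 with no background correction and 12 with a normexp offset of 50, and no gene passed with 3 h counted as early (856 with an unadjusted p under 0.05) or with no detection filter (1817 of 19689 genes).

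**Figure D1:**
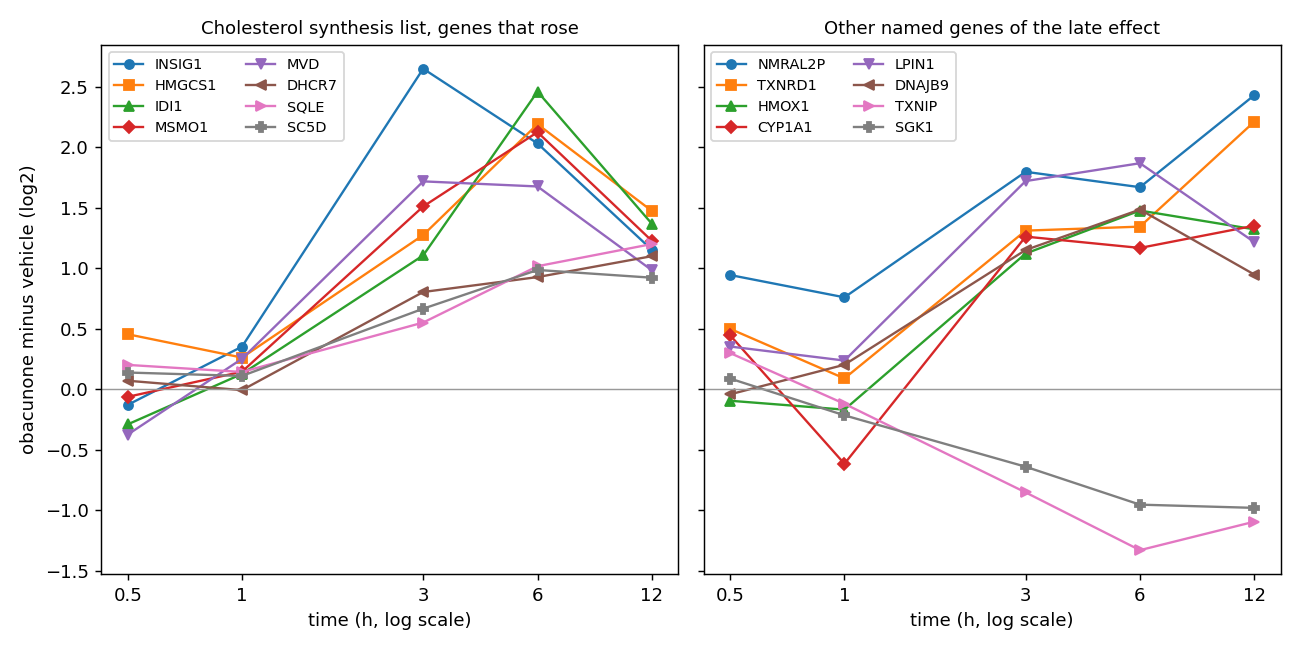
Log2 obacunone minus vehicle (vertical axis) at each collection time in hours (horizontal log axis) for the 8 cholesterol genes that rose and for 8 other genes past the late test, with 1 point per pair of arrays. INSIG1 stood at 2.65 at 3 h and 1.15 at 12 h, TXNRD1 at 1.31 and 2.21, and TXNIP at -0.85 and -1.10.

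The gene lists asked whether genes of a known pathway moved together late. Of 12 measured genes of cholesterol synthesis and uptake, 8 rose and 0 fell over all genes tested, and 11 rose adjusted over the list alone. The list median was 0.93 log2, and camera, which compares a list with all other genes, gave an adjusted p of 5.49e-24 (adjusted p = 0.225 with an estimated correlation). The 3 genes that rose over the list alone were CYP51A1 (0.92 ± 0.19), LSS (0.68 ± 0.15) and FDPS (0.63 ± 0.16), which were chosen after their values were seen. The medians at 0.5, 1, 3, 6 and 12 h were -0.17, 0.14, 0.84, 1.08 and 1.11, and the last 3 lay above all 10000 random lists of like expression.

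Of 19 measured NRF2 targets, genes of the response to oxidants and electrophiles, 2 rose (TXNRD1 and HMOX1) and 0 fell, with 10 rises adjusted over the list alone. The camera adjusted p was 1.93e-11 (adjusted p = 0.307 with an estimated correlation). GCLM, a subunit of the enzyme that starts glutathione synthesis, had 0.94 ± 0.20, and UGDH had 0.92 ± 0.19. The list medians at 3, 6 and 12 h were 0.19, 0.29 and 0.84. At 12 h the mean level of 166 small non-coding RNA genes also differed between the arrays, by -0.29 log2. Of 6 measured AHR targets, 1 rose (CYP1A1), 0 fell, and 2 rose adjusted over the list alone, with CYP1B1 at 0.86 ± 0.19. The camera adjusted p was 4.03e-05 (adjusted p = 0.282 with an estimated correlation).

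Stress lists had smaller differences. Of 13 genes of chaperones of the endoplasmic reticulum and the unfolded protein response, 1 rose (DNAJB9) and 0 fell. Adjusted over the list alone 2 rose, and MANF had 0.45 ± 0.14. The list median was 0.25 (camera adjusted p = 4.03e-05; adjusted p = 0.282 with an estimated correlation). Of 16 genes of the ATF4 and CHOP stress response, 0 passed limma over all genes tested and 3 rose adjusted over the list alone. PPP1R15A, which reverses the stress arrest of translation, had 0.73 ± 0.15, and DDIT3, which encodes CHOP, had 0.54 ± 0.18. The median was 0.27 (camera adjusted p = 0.000257; adjusted p = 0.282 with an estimated correlation). Of 15 heat shock genes, 0 passed limma over all genes and 1 rose adjusted over the list alone. HSPA1A had 0.83 ± 0.19, and the median was 0.12 (camera adjusted p = 0.000272; adjusted p = 0.307 with an estimated correlation). The heat shock medians at 0.5, 1, 3, 6 and 12 h were 0.36, -0.08, 0.14, 0.11 and 0.41, highest at 0.5 and 12 h. With scaling to the 75th percentile the 12 h median was 0.11.

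A further 4 lists passed the camera test with no member past limma over all genes. Of 10 p53 targets, 3 rose and 2 fell adjusted over the list alone, with a median of 0.25 (camera adjusted p = 0.0464; adjusted p = 0.307 with an estimated correlation). The cell cycle inhibitor CDKN1A had 0.79 ± 0.15 and ZMAT3 had -0.63 ± 0.18. Of 13 genes of hypoxia and glycolysis, 4 rose adjusted over the list alone, among them BNIP3 (0.54 ± 0.16), with a median of 0.06 (camera adjusted p = 0.0251; adjusted p = 0.673 with an estimated correlation). Of 11 ribosome biogenesis genes, 1 fell adjusted over the list alone (RRP12, -0.50 ± 0.14), with a median of -0.14 (camera adjusted p = 0.0212; adjusted p = 0.307 with an estimated correlation). Of 10 basal keratinocyte genes, 0 passed limma adjusted over the list alone. KRT15 had -0.55 ± 0.21, and the median was -0.27 (camera adjusted p = 0.0464; adjusted p = 0.404 with an estimated correlation). Without the 12 h pair the p53 list had an adjusted p of 0.162, the hypoxia list 0.692 and the basal list 0.121.

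**Figure D2:**
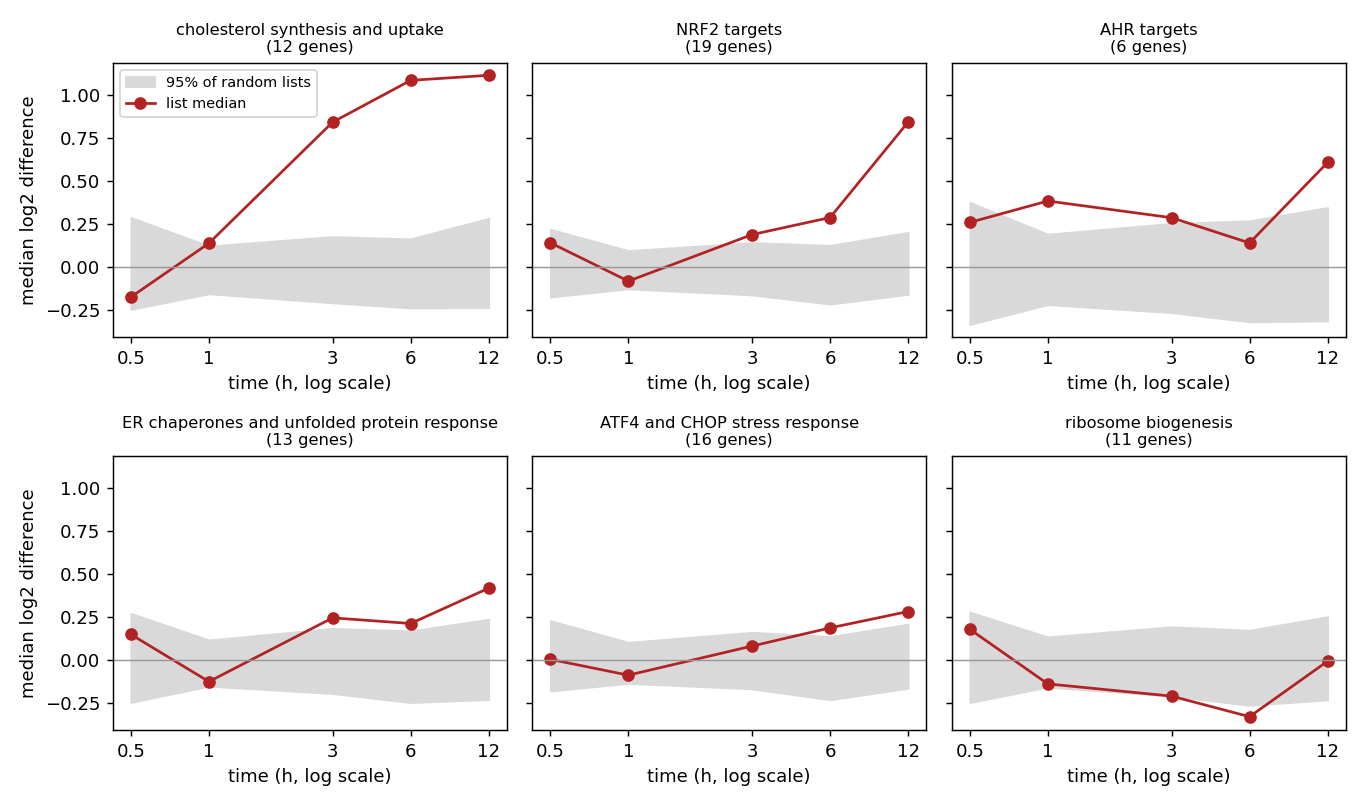
Median log2 obacunone minus vehicle of 6 gene lists (red, vertical axis) at each collection time in hours (horizontal log axis), with the central 95% of the medians of random lists of the same size and like expression in grey. The cholesterol median was -0.17 at 0.5 h and 1.11 at 12 h, and the ribosome biogenesis median was -0.33 at 6 h and 0.00 at 12 h.

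With the directional test of fry, which tests a list without reference to other genes, no list passed for the late effect. Cholesterol genes had an adjusted p of 0.0766, AHR targets 0.0854 and NRF2 targets 0.232. The mixed test of fry gave adjusted p of 0.00352, 0.0017 and 0.0315 for them. That test does not ask whether members moved the same way. It also passed lists with no camera call, such as glucocorticoid and p38-JNK stress genes (0.00041) and interferon response genes (0.0315). The other 14 lists did not pass the late camera test. Of 8 glucocorticoid and p38-JNK stress genes, SGK1 fell over all genes, and adjusted over the list alone SGK1 fell and GADD45B (0.70 ± 0.17) rose (camera adjusted p = 0.552). Of 11 genes of the BCL2 family list, which also holds the apoptosis inhibitor XIAP, 3 rose adjusted over the list alone, with PMAIP1 at 0.80 ± 0.19, XIAP at 0.65 ± 0.18 and BIK at 0.52 ± 0.15 (camera adjusted p = 0.0569). Of 11 inflammatory and NF-kB genes, 2 rose adjusted over the list alone, IL1A (0.56 ± 0.17) and PTGS2 (0.54 ± 0.16). That list had a median of -0.01, a mean of 0.03 and an upward camera test (adjusted p = 0.721). Of 14 ERK feedback genes, HBEGF, a growth factor gene, rose adjusted over the list alone (0.80 ± 0.16; camera adjusted p = 0.350). Of 11 keratinocyte differentiation genes, TGM1, a transglutaminase of the cornified envelope, fell adjusted over the list alone (-0.64 ± 0.17; camera adjusted p = 0.491). Of 9 circadian clock genes, BHLHE40 rose (0.67 ± 0.17) and DBP fell (-0.63 ± 0.21) adjusted over the list alone (camera adjusted p = 0.896). Of 8 LXR targets and fatty acid synthesis genes, SCD rose adjusted over the list alone (0.57 ± 0.17; camera adjusted p = 0.491).

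No member of the remaining lists passed limma, over all genes or adjusted over the list alone. The 14 immediate early genes had a median of 0.03 (camera adjusted p = 0.491), and the 14 interferon response genes 0.06 (adjusted p = 0.551). The 18 mitosis genes had a median of 0.04 (adjusted p = 0.551) and the 13 TGF-beta and YAP targets -0.08 (adjusted p = 0.747). The 16 DNA replication genes had a median of 0.01, a mean of -0.05 and a downward test (adjusted p = 0.551). The 6 metallothionein genes had a median of 0.03, a mean of -0.03 and a downward test (adjusted p = 0.896). Of 19 markers of fibroblasts, melanocytes, immune and endothelial cells, 3 were measured (COL1A1, COL1A2 and CD68), with a median of -0.12 (adjusted p = 0.551).

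The average comparison asked which transcripts differed over all 5 matched times (n = 5 pairs), and it shares its arrays with the late comparison. NMRAL2P rose (1.52 ± 0.20, adjusted p = 0.0392), and so did SPACA6 (0.78 ± 0.11, adjusted p = 0.0392), each higher at 5 of 5 times. SPACA6 had 0.62, 0.74, 0.96, 0.72 and 0.83 in the order of the times. The small nucleolar RNA SNORA12 fell (-1.02 ± 0.15, adjusted p = 0.0438). This gene was chosen after its values were seen. Small non-coding RNAs as a class were lower at 0.5 and 12 h, and with their mean level as a covariate SNORA12 had -0.78 ± 0.12 (adjusted p = 0.22) and no gene passed. Of the 24 lists, 6 passed camera, all upward, and 0 of their members passed limma over all genes. Cholesterol genes had a median of 0.60, with 10 rises adjusted over the list alone (camera adjusted p = 4.06e-09; adjusted p = 0.649 with an estimated correlation). NRF2 targets had a median of 0.41, with 8 such rises (camera adjusted p = 4.99e-06; adjusted p = 0.649 with an estimated correlation). AHR targets had 4 such rises (camera adjusted p = 0.00017; adjusted p = 0.59 with an estimated correlation). The heat shock, endoplasmic reticulum and ATF4 lists had camera adjusted p of 0.000815, 0.00467 and 0.0255 (adjusted p = 0.649 with an estimated correlation for each of them). No list passed fry for the average (smallest adjusted p = 0.265).

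For the average, limma called 3 genes, 2 up and 1 down, and 1214 had an unadjusted p under 0.05. The count was 1 without the 0.5 h or the 1 h pair, 8 without the 6 h pair, and 0 without the 3 h pair (1298 with an unadjusted p under 0.05) or the 12 h pair (716). It was 0 with no background correction (1275), a normexp offset of 50 (1276), no detection filter (1979) or the authors' values (1289).

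The early comparison asked which transcripts differed at 0.5 and 1 h (n = 2 pairs). No gene passed limma, with 661 at an unadjusted p under 0.05 and a smallest adjusted p of 0.691. The genes with the smallest p are given as values. Levels were higher with obacunone for NF1, a regulator of RAS (0.95 ± 0.20), NPIPB5 (1.07 ± 0.23), GOLGA8B (0.93 ± 0.21), NFYC-AS1 (0.90 ± 0.19) and UCN2, a urocortin (0.89 ± 0.19). Levels were lower for TERC, the RNA of telomerase (-1.26 ± 0.27), SCARNA14 (-1.15 ± 0.24), SCARNA18 (-1.03 ± 0.25), the histone gene H2BC15 (-0.75 ± 0.19) and GALNS (-0.70 ± 0.18). TERC and the SCARNA genes are small non-coding RNAs, whose mean level over 166 genes differed by -0.26 log2 at 0.5 h.

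The late minus early comparison asked whether the difference changed with time. No gene passed limma, with 546 at an unadjusted p under 0.05 and a smallest adjusted p of 0.356. Values with the smallest p were positive for INSIG1 (1.83 ± 0.36), MSMO1 (1.58 ± 0.28), MVD (1.52 ± 0.29), HMOX1 (1.44 ± 0.23) and LPIN1 (1.31 ± 0.25). They were negative for TXNIP (-1.18 ± 0.25), ZNF346 (-1.07 ± 0.26), CYP24A1, a vitamin D hydroxylase (-1.02 ± 0.25), TRIM61 (-1.01 ± 0.25) and ZNF486 (-0.97 ± 0.25). Without the 12 h pair, 1 gene passed.

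At each single time, differences of at least 2-fold were counted as values with no test, since each rests on 1 array per agent. At 0.5 h, 46 genes were higher and 42 lower with obacunone, a balance that depended on processing: 35 of 101 were higher with scaling to the 75th percentile and 10 of 24 with no background correction. GIGYF2, a translation repressor, stood at 1.42, GOLGB1, a Golgi protein, at 1.37 and KMT2A, a histone methyltransferase, at 1.34. Lower were GADD45GIP1 (-1.65), TERC (-1.62), the DNA repair gene TDP1 (-1.54) and RPPH1, the RNA of ribonuclease P (-1.38). At 1 h, 8 genes were higher, such as ZNF264 (1.21) and NF1 (1.14), and 5 lower, such as HHIPL1 (-1.34) and UXS1 (-1.07). At 3 h, 46 were higher and 28 lower. INSIG1 was at 2.65, the snoRNA host genes SNHG9 at 2.09 and SNHG12 at 1.61, ZC3H12A, a ribonuclease, at 1.92 and TNFSF9, the ligand of a receptor on T cells, at 1.69. SHROOM4 (-1.31) and PIGV (-1.26) were lower.

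At 6 h, 53 genes were higher and 11 lower. The cholesterol genes IDI1 (2.46), HMGCS1 (2.19), MSMO1 (2.13) and INSIG1 (2.03) led the higher ones, and NAV1 (-1.45), TXNIP (-1.33) and TGM1 (-1.09) were among the lower. At 12 h, 54 were higher and 53 lower (41 of 118 higher with scaling to the 75th percentile). NMRAL2P (2.43), TXNRD1 (2.21), CYP4F11 (2.09), the aldo-keto reductases AKR1C3 (1.68) and AKR1B10 (1.62), the cystine transporter SLC7A11 (1.57) and GCLM (1.57) were higher. SCARNA18 (-1.63), MMP12, a metalloproteinase (-1.53), TERC (-1.51), the transcription factors SOX2 (-1.49) and DBP (-1.44) were lower. The mean of the small non-coding RNAs differed by -0.26 at 0.5 h and -0.29 at 12 h, against -0.00, 0.05 and 0.00 at 1, 3 and 6 h.

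The same 9 genes were at least 2-fold higher at 3, 6 and 12 h: CYP1A1, HMGCS1, HMOX1, IDI1, INSIG1, LPIN1, MSMO1, NMRAL2P and TXNRD1. None was 2-fold lower at all 3 times. The times shared 18 higher genes at 3 and 6 h, where 0.231 would be shared at random, and 14 at 6 and 12 h (0.271 at random). They shared 16 lower genes at 0.5 and 12 h (0.211 at random). Across genes, the differences at 0.5 and 12 h correlated with r = 0.524 and those at 3 and 6 h with r = 0.356, and genes are not independent replicates. The 12 h differences correlated less with those at the other late times (r = 0.036 with 3 h and 0.151 with 6 h). As background, a vehicle array differed 2-fold from the vehicle array before it in 24, 12, 25, 22 and 42 genes. Against the 0 h vehicle array the totals were 24, 42, 29, 116 and 272, which exceed those of obacunone against vehicle at 1, 6 and 12 h. With no background correction, the totals at 0.5, 1, 3, 6 and 12 h were 24, 0, 27, 19 and 39 in place of 88, 13, 74, 64 and 107.

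**Figure D3:**
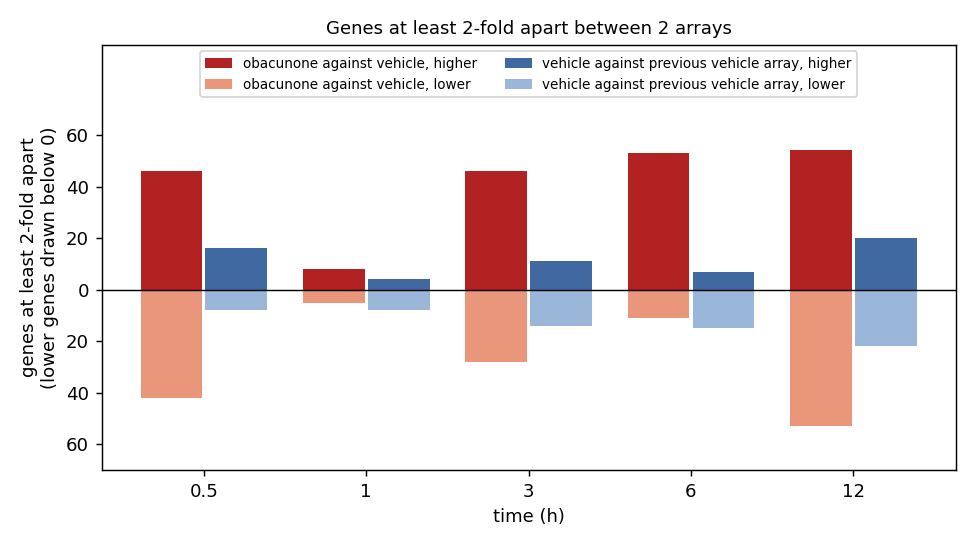
Number of genes at least 2-fold higher (bars above 0) or lower (bars below 0) at each collection time in hours, for obacunone against vehicle (red) and for each vehicle array against the vehicle array before it (blue). The red totals were 88, 13, 74, 64 and 107 and the blue ones 24, 12, 25, 22 and 42.

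The vehicle course asked which transcripts changed in vehicle cells over the 12 h after fresh medium, as a slope per doubling of hours plus 1 (n = 6 arrays). TNFSF10, the death ligand TRAIL, rose (slope 0.68 ± 0.06, adjusted p = 0.000279; log2 4.60 at 0 h, 7.23 at 12 h). The stress genes CHAC1 (0.63 ± 0.09, adjusted p = 0.0039) and DDIT4 (0.63 ± 0.09, adjusted p = 0.0039) rose, as did SOX2 (0.59 ± 0.08, adjusted p = 0.00543) and VAV3 (0.49 ± 0.07, adjusted p = 0.00543). TNFAIP3, an inhibitor of NF-kB, fell (-0.78 ± 0.06, adjusted p = 0.000189; log2 7.97 at 0 h, 5.33 at 12 h). SOCS1, an inhibitor of cytokine signals (-0.59 ± 0.05), FST, which binds activin (-0.55 ± 0.05), PTGS2, a cyclooxygenase (-0.55 ± 0.06), EDN1 (-0.52 ± 0.07) and THBS1, a matrix protein (-0.51 ± 0.06), fell as well. TNFSF10 and CHAC1 at 0 h lay under the lowest detected value of that array (5.06), and SOCS1 at 12 h lay under that of its array (5.10), so the sizes of these 3 changes are not exact. Of 16 ATF4 and CHOP genes 3 rose (ASNS, CHAC1 and DDIT4), of 11 NF-kB genes 3 fell (TNFAIP3, PTGS2 and RELB) and of 14 immediate early genes 2 fell (FOSB and FOSL1). As values with no test, the 0.5 h vehicle array stood above the 0 h array for EGR1 by 1.58, FOS by 1.18 and SNHG12 by 1.32.

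In the limma fit of the vehicle course, 95 of 10556 genes passed, 34 up and 61 down, and 1515 had an unadjusted p under 0.05. The count was 260 without the 3 h array, 41 without the 0 h, 48 without the 1 h, 38 without the 6 h and 16 without the 12 h array. It was 62 with no background correction and 3 with no detection filter.

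**Figure D4:**
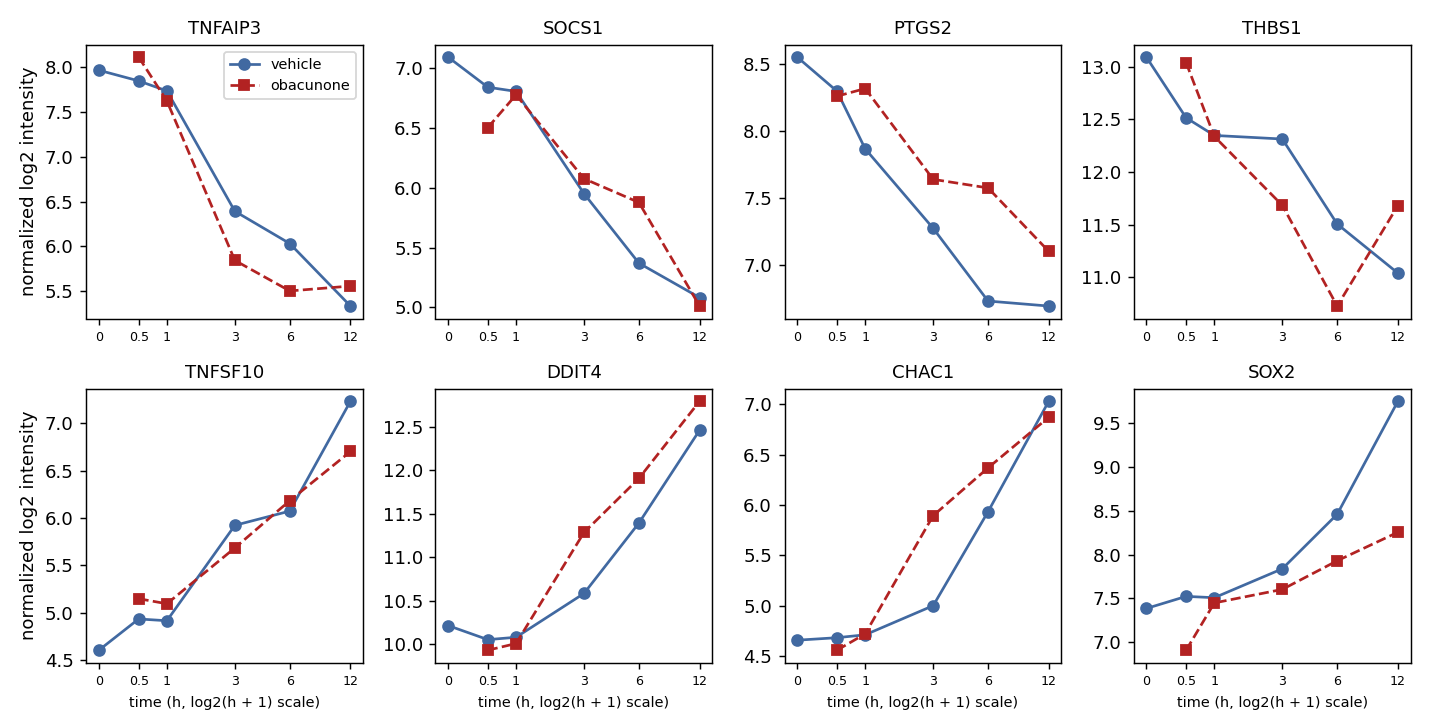
Normalised log2 intensity (vertical axis) of 8 genes at each collection time (horizontal axis, hours on a scale of log2 of hours plus 1) in vehicle cells (blue, solid) and obacunone cells (red, dashed), with 1 array per point. TNFAIP3 went from 7.97 at 0 h to 5.33 at 12 h in vehicle cells, and TNFSF10 from 4.60, which is under the lowest detected value of the 0 h array (5.06), to 7.23.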

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

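The camera tests on late minus early differences, the tests on features with no gene symbol and the tests of explanations in this part were chosen only after the results were seen. Some gene lists stood higher against vehicle late than early, although no single gene passed limma for that difference (546 with an unadjusted p under 0.05). The cholesterol list had a median late minus early difference of 0.99 log2 (camera adjusted p = 1.77e-20; adjusted p = 0.281 with an estimated correlation), and NRF2 targets had 0.34 (camera adjusted p = 2.1e-07; adjusted p = 0.571 with an estimated correlation). The endoplasmic reticulum list had a median of 0.20 (camera adjusted p = 0.00276; adjusted p = 0.467 with an estimated correlation) and the ATF4 and CHOP list 0.30 (0.00433; adjusted p = 0.467 with an estimated correlation). The BCL2 family list had 0.25 (0.0099; adjusted p = 0.467 with an estimated correlation) and immediate early genes 0.18 (0.0439; adjusted p = 0.632 with an estimated correlation). No list passed the directional test of fry for this difference (smallest adjusted p = 0.288). The mixed test of fry gave adjusted p of 0.0364 for cholesterol genes, 0.282 for NRF2 targets and 0.00211 for glucocorticoid and p38-JNK stress genes. Immediate early genes had medians of -0.03 at 0.5 h and -0.17 at 1 h against 0.03 late, so their difference from vehicle was not larger late. The 6 lists were picked out because the difference between early and late times passed a test of its own.

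Features with no gene symbol were outside the comparisons of genes, and whether they are further probes of the same genes was not tested. Of 4537 such features, 7 passed the late test (6 up and 1 down), and the 2 with the smallest p had log2 differences of 1.88 and 1.89. For late minus early, 2 passed, 1 up and 1 down. None passed limma for the average effect (345 with an unadjusted p under 0.05) or the early effect (326).

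Cholesterol genes and NRF2 targets both rose late, with different courses. Their medians at 3, 6 and 12 h were 0.84, 1.08 and 1.11 for cholesterol genes and 0.19, 0.29 and 0.84 for NRF2 targets. For these rises 2 explanations other than obacunone were tested. If arrays that differ in small RNA level made the cholesterol rise, the level as a covariate should remove it, but the list kept a late median of 0.91. For NRF2 targets the 0.5 h pair, whose small RNA levels differ like those of the 12 h pair, had a median of 0.14 against 0.84 at 12 h, which argues against that axis as the whole cause. The values also argue against a fall in vehicle cells alone. Against the 0 h vehicle array the lowest late cholesterol median with obacunone was 1.01, and the NRF2 median at 12 h was 0.68. Vehicle medians against the same array reached 0.37 for cholesterol genes at 6 h and -0.19 for NRF2 targets at 12 h. All of these values rest on 1 array at 0 h. Obacunone itself was tested in the late comparison, with 8 of 12 cholesterol genes and 2 of 19 NRF2 targets past limma. In the average comparison, which shares its arrays, 0 genes of either list passed limma. The list tests and the splits of arrays also compared the agents, and no further test of obacunone as the cause was run.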

How the results depend on the processing

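The filter on signal, the small RNA level as a covariate, leaving out the 0.5 and 12 h pairs together, and the late lists without the 12 h pair are tests that were chosen only after the data were seen. No gene past its test reversed its direction under any alternative in which it was measured (394 of 394 values for the late effect, 57 of 57 for the average and 1785 of 1785 for the vehicle course), and no list past camera did in the alternatives run for lists, but the balance of 2-fold higher and lower genes turned at 0.5 and 12 h under some. Of the main values and counts under the alternatives, 106 stayed on their side of the threshold or within 1.5 times, 59 moved and 21 lost their call. For single named genes 501 kept their call and 125 lost it, all in the same direction, and the lists with no call had none under the alternatives (106 of 106). Signal over background limits what dim genes can show: the lowest detected log2 value was 5.01 to 5.13 per array. Scaling to the 75th percentile moved the median of all genes by -0.103 log2 at 12 h, so the sign of small differences at that time depends on the scaling: the ribosome biogenesis median went from 0.00 to -0.18 and the DNA replication median from 0.08 to -0.07. Cholesterol genes (1.02) and NRF2 targets (0.70) kept theirs. Arrays were blocked by time, and beyond that no paired analysis was possible because the labels number no replicates. Except where a reason is given, the cause was not tested.

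The average effect (3 genes with limma) gave 0 with no background correction, normexp with an offset of 50, the authors' values and no detection filter, which tests 19689 genes. It gave 1 with an intensity trend and robust prior, and 1 with no time block, with or without the 0 h array. Of the added alternatives, it gave 0 without the 0.5 and 12 h pairs (1182 with an unadjusted p under 0.05) and 0 with the small RNA covariate (1259). Leaving out 1 pair gave 0 to 8 genes: 0 without 3 h or 12 h, 1 without 0.5 h or 1 h, 8 without 6 h.

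The late effect (22 genes) gave 11 with no background correction and 12 with normexp and an offset of 50, all among the 22. It gave 0 with no detection filter (1817 with an unadjusted p under 0.05) and 0 with 3 h counted as early (856). The added filter on signal gave 34 and the small RNA covariate 65, each with all 22 among them, and the added fit without the 0.5 and 12 h pairs gave 18, with 11 of the 22 among them. Leaving out 1 pair gave 7 (3 h) to 50 genes (0.5 h or 1 h, which give the same late fit). It gave 10 without 6 h and 31 without 12 h, of which 16 were among the 22. The early effect had 0 genes under all alternatives that kept both early pairs (523 to 1282 with an unadjusted p under 0.05). Without the 0.5 h or the 1 h pair it rests on 1 pair, with the spread taken from the late pairs, so that fit says little. Late minus early had 0 (337 to 1092), except 1 without 12 h in a range of 0 to 1.

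The vehicle course (95 genes) gave 62 with no background correction, 3 with no detection filter and 251 with the small RNA covariate. Leaving out 1 array gave 16 (12 h) to 260 (3 h), with 41 without 0 h, 48 without 1 h and 38 without 6 h.

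Genes at least 2-fold apart at 0.5, 1, 3, 6 and 12 h numbered 1258, 259, 717, 765 and 1054 at a 1.5-fold threshold and 2, 0, 9, 9 and 9 at 3-fold, by construction. They numbered 24, 0, 27, 19 and 39 with no background correction, 27, 0, 32, 20 and 47 with normexp and an offset of 50, and 28, 0, 32, 22 and 50 with the authors' values. These keep more background in the signal, which shrinks ratios. In these 3 settings, higher genes were 10 of 24, 11 of 27 and 12 of 28 at 0.5 h and 21 of 39, 23 of 47 and 24 of 50 at 12 h. Detection on both arrays left 4 at 1 h. Scaling to the 75th percentile changed the share of higher genes, to 35 of 101 at 0.5 h (from 46 of 88), 54 of 75 at 3 h (46 of 74) and 41 of 118 at 12 h (54 of 107).

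With an estimated correlation between genes, every camera call on a list was lost. For the late effect the adjusted p was 0.225 for cholesterol, 0.282 for AHR, ATF4 and endoplasmic reticulum lists, 0.307 for NRF2, heat shock, p53 and ribosome biogenesis, 0.404 for basal keratinocyte and 0.673 for hypoxia. For the average it was 0.59 for AHR and 0.649 for cholesterol, NRF2, ATF4, endoplasmic reticulum and heat shock. By construction this setting counts the correlation of list members, which was up to 0.76 for cholesterol genes in the average fit. That fit has 1 agent term over all times, so changes of the effect with time enter this correlation. In the late fit, with separate early and late terms, it was 0.22 for cholesterol genes and 0.55 for NRF2 targets. In the added alternatives, the late call was lost without the 12 h pair for the basal (0.121), p53 (0.162) and hypoxia lists (0.692), and with the small RNA covariate for p53 (0.0999) and hypoxia (0.391).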

Other observations

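Apart from the counts of other sample splits, which were set before the data were examined, the tests in this part were chosen only after the results were seen. Host genes of small nucleolar RNAs formed a group with higher levels in obacunone cells in the middle of the course. The 14 measured host genes had median differences of 0.03, -0.01, 0.72, 0.52 and 0.19 log2 at 0.5, 1, 3, 6 and 12 h, in a set put together after SNHG9 and SNHG12 were seen among the largest rises. Without the 4 host genes that were 2-fold higher at 3 h, the other 10 had medians of 0.64 at 3 h and 0.47 at 6 h, above all 10000 random lists. The 4 left out were SNHG9 (2.09 at 3 h), SNHG12 (1.61), SNHG1 (1.195) and SNHG5 (1.04). SNHG7, at 0.92, was among the other 10. Against the 0 h vehicle array, the vehicle medians were 0.59, 0.60, 0.21, 0.52 and 0.49, and the obacunone medians 0.60, 0.57, 0.90, 0.99 and 0.57. A low vehicle array at 3 h alone does not account for this, since 8 of 14 host genes were higher on the 6 h obacunone array than on every vehicle array (10 of 14 on the 3 h array). Slower nonsense-mediated decay, which degrades many of these transcripts, may contribute: 6 measured decay targets of another kind had medians of 0.37 at 3 h and 0.13 at 6 h. The lower of their percentiles among random lists was 87.5, which neither excludes nor bears out this cause.

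A filter on signal in place of detection p added 446 genes and left out others, with 10745 tested in place of 10556. Detection p had left out 119 named features with a mean log2 of at least 8, all with p-values between whole steps. Among the added genes were GCLC, the catalytic partner of GCLM in glutathione synthesis, with a late difference of 1.25 ± 0.22 (adjusted p = 0.0271), and the stress factor ATF3, with 0.91 ± 0.15 (adjusted p = 0.0169). AKR1C2 had 1.00 ± 0.22 (adjusted p = 0.079). These 3 genes were chosen after their values were seen.

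In vehicle cells after fresh medium, 11 of 24 lists passed camera, 4 up and 7 down. With the directional test of fry the NF-kB and circadian clock lists passed (adjusted p = 0.0428 for both). The NF-kB list fell (camera adjusted p = 6.75e-09; adjusted p = 0.281 with an estimated correlation), with 7 of 11 members down adjusted over the list alone. The ATF4 and CHOP list rose (9.80e-05; adjusted p = 0.281 with an estimated correlation), with 6 of 16 members up. Immediate early genes fell (0.00012; adjusted p = 0.289 with an estimated correlation), with 5 of 14 members down, and so did TGF-beta and YAP targets (0.00323; adjusted p = 0.281 with an estimated correlation), with 7 of 13 members down and 3 up. The other downward tests were those of basal keratinocyte genes (0.0127; adjusted p = 0.289 with an estimated correlation; 2 of 10 members down), ribosome biogenesis (0.0129; adjusted p = 0.472 with an estimated correlation; 0 of 11 down), the circadian clock (0.0146; adjusted p = 0.281 with an estimated correlation; 4 of 9 down and 1 up) and glucocorticoid and p38-JNK stress genes (0.0361; adjusted p = 0.314 with an estimated correlation; 2 of 8 down and 1 up). The other upward tests were those of interferon response genes (0.0242; adjusted p = 0.341 with an estimated correlation; 3 of 14 up), metallothioneins (0.029; adjusted p = 0.472 with an estimated correlation; 2 of 6 up and 1 down) and LXR targets (0.0361; adjusted p = 0.33 with an estimated correlation; 1 of 8 up).

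The 166 small non-coding RNA genes had a lower mean with obacunone at 0.5 h (-0.26) and 12 h (-0.29), the pairs whose lists of 2-fold lower genes shared 16 members. A lowering of like size was not seen at the other times: the highest of their median differences at 1, 3 and 6 h was 0.041. A smaller effect held over all times cannot be excluded, since each time has 1 pair and vehicle arrays differed among themselves. A yield of small RNA that varies between arrays whatever the agent is neither borne out nor excluded. The mean level ranged over 0.34 log2 among the 6 vehicle arrays, but over 0.20 without the 0.5 h vehicle array, which is itself part of a pair. An effect of obacunone at 0.5 and 12 h alone was not tested and stays open as well.

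Other splits of the arrays test whether the groups matter. For the average effect, 5 of 100 drawn splits of the 10 matched arrays (of 126 possible) called as many genes as the real 3, so chance is not excluded. The highest other split called 27 genes, several times the real count, which points to a structure of the samples. Among the 13 drawn splits that part all 5 pairs, the real one called 3 and the highest other 2. For the late effect, the real split called 22 genes and the highest other split 0. The 10 splits are too few for a share under 0.05 (the real split, 1 of 10, was the only one to call as many). Most of them also put both arrays of some times on the same side, where the time block absorbs the pair. In the average comparison, the split that called 27 genes also did not part all 5 pairs. How much room the late splits had to call genes was not tested, so their counts of 0 say little. For the vehicle course, 2 of 100 orders of the 6 arrays, the real order among them, called as many genes as the real 95. That share is under 0.05, but with 1 array per time and a wrong order that called more, chance is not excluded. The highest other order called 316 genes. It kept the arrays at 0, 6 and 12 h and exchanged those at 0.5, 1 and 3 h, which points to a structure among the early arrays.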
